A study of Mus musculus with 12 samples.

How the data were processed

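Whole spinal cord RNA from 12 mice aged 8 weeks was measured by RNA sequencing. Per the labels, 6 mice were wild type (WT) and 6 were heterozygous for the ETAQ deletion in Gars (ETAQ/+), with 3 females and 3 males of each genotype, on a mixed B6J;FVB background. The titles number the mice from 1 to 12, and each library is named here by that number. Per the labels' protocols, tissue was lysed in TRIzol, RNA was purified on miRNeasy columns with a DNase step, polyA RNA was selected, and libraries were sequenced as 75 bp paired reads on a NextSeq instrument. The protocol names both a KAPA Stranded mRNA-Seq kit and a KAPA mRNA HyperPrep kit without saying which library was made with which.

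Per the submitters' processing notes, the tools were Bowtie2 2.2.0 and RSEM 1.2.12, which assigns each read pair to transcripts in proportion to an estimate and so can divide reads between near-identical genes. The genome build, the annotation and the strand setting of the counting were not given in the sources used here. The authors' deposited tables hold, per the file headers, an expected count for each of 38924 Ensembl genes in each mouse. Expected counts are not normalised, and 15.4% of the values (genes by libraries) were not whole. The deposited tables also hold TPM values, which the authors' software scaled by gene length and library total, per the file headers. The FPKM values in the deposited tables, scaled by length and depth per the file headers, were not tested, and neither was TPM.

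The expected counts were rounded to whole numbers and analysed in R 4.3.3. Library totals ranged from 23595929 to 41452662 expected counts, and 3 counts, the upper limit that a count of 0 allows, corresponded to 0.0724 to 0.127 CPM (counts scaled by library total) depending on the library. Such limits cover counting error only, since the libraries carry no molecular identifiers. Genes were kept with the filterByExpr function of edgeR 4.0.16 applied to the 4 genotype-by-sex groups, which left 17189 genes. Libraries were scaled by TMM, with factors from 0.975 to 1.02, and the values called normalised CPM below use those factors. Means are given with the standard deviation (SD) over mice.

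The genotype effect was tested with edgeR's robust quasi-likelihood test with sex as a covariate. The effect within each sex, and the difference of the 2 effects (the interaction), came from a fit of the 4 groups in which all 12 libraries share the estimate of the spread. The sex effect was tested with genotype as a covariate. Adjusted p values are Benjamini-Hochberg values from edgeR over all genes tested, with a threshold of 0.05. Each log2 fold change is given with its standard error (SE), the absolute log2 fold change divided by the square root of the F statistic. All these tests are two-sided.

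A set of 42 gene lists was written for stress responses, tRNA synthetases, cell types of the cord and of neighbouring tissue, organelles and regulatory pathways. Of their 703 entries, 675 were tested and 5 matched no gene of the tables. Each list was tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with a correlation estimated from the data. The rotation test fry was run beside it. Calls were also counted after adjustment over each list alone.

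Gene positions came from GENCODE M21 (GRCm38), matched by Ensembl ID for 96.6% of the IDs, including 16949 of the tested genes. Since the authors' build was not given, positions describe this reference only. The share of each gene's 75-base sequences that also occur in transcripts of another gene was computed from the same release, sampling 1 in 16 of them, and genes with a share of at least 5% were treated as uncertain. Overlap of exons with other genes was taken from the same annotation. Calls near Gars were counted within 10 Mb on chromosome 6 and compared with all other autosomal genes by Fisher's exact test.

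The groups, tests, lists, alternatives and naming rule were fixed before the data were examined. The rule named Gars, up to 12 higher and 12 lower genes with the smallest p among genotype calls of the same sign in both sexes, up to 4 called members per list, the 2 members with the smallest p for chosen lists without calls, Xist and 4 Y-linked genes with up to 5 autosomal calls for sex, and Nnt. Genes without a symbol were counted and not named. The division of the libraries into mice 1 to 6 and mice 7 to 12, the look at chromosome 14 and the alternatives built on them were added after seeing the data.

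The fits were tested on simulated data, in which genes were given known fold changes and counts were drawn from the real means and library sizes. For the genotype effect, 46% of genes changed by 1.2-fold, 64% at 1.5-fold, 88% at 2-fold and 93.9% at 4-fold were called, and 3.33% of the calls were false. In females the shares were 18%, 44%, 84% and 83.7%. In males they were 14%, 54%, 74% and 83.7%. For sex they were 40.8%, 72%, 83.7% and 89.8%. For the interaction they were 4.08%, 41.7%, 64% and 77.6%. Genes that also differ by mouse number were not simulated apart, so these shares do not describe them.

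Alternatives were the median-ratio size factors of DESeq2 (RLE), no filter on low counts, a filter of at least 1 CPM in at least 6 libraries, the Wald test of DESeq2 1.42.0, limma-voom, a fit without robust shrinkage, 1 surrogate variable from sva 3.50.0, no sex covariate, a threshold of 0.10, and each library left out in turn. The mouse number covariate, a genotype term for each set of mice in a fit of all 12 libraries, and the removal of chromosome 14 were added later. As a check for a library deposited more than once, counts were compared for all 66 pairs of libraries, and the lowest chi-square per degree of freedom was 6.24. No pair was therefore within sampling noise, and all 12 libraries were counted as separate mice, as the labels number them.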

Results

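Spinal cord transcriptomes of 6 WT and 6 ETAQ/+ mice, with 3 females and 3 males of each genotype, were compared at 8 weeks of age. Gars encodes glycyl-tRNA synthetase, the enzyme that charges tRNA with glycine, and the ETAQ deletion takes a run of amino acids, spelled by its name, out of that enzyme. Dominant variants of the human gene cause an axonal neuropathy of motor and sensory nerves, and the comparison asks which transcripts of the whole cord change in heterozygous mice. Library totals in expected counts were 33382112, 32219495, 26194571, 41452662, 23595929 and 30484084 for mice 1 to 6, and 27992800, 27394828, 30333041, 32801037, 28260776 and 29876316 for mice 7 to 12. Between 20805 and 21858 genes had a count above 0 in a library, and mitochondrially encoded transcripts took 7.88% to 11.1% of the counts.

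Gars (ENSMUSG00000029777, chromosome 6, 55038007 to 55079500, GRCm38) was read in every library first. It stood at 145 ± 5.79 normalised CPM (SD, n = 6) in ETAQ/+ and at 127 ± 4.95 in WT (n = 6), a log2 fold change of 0.19 ± 0.03 (SE) with an edgeR adjusted p of 0.00408. The ETAQ/+ mice ranged from 136 to 151 and the WT mice from 119.7 to 133, without overlap. Within mice 1 to 6 the log2 fold change was 0.18 (adjusted p = 0.146), and within mice 7 to 12 it was 0.20 (adjusted p = 0.0871). Gene counts do not separate the normal from the deleted allele, so these values do not check the genotype labels. The sex labels were checked with Xist, the RNA that silences an X chromosome, at 395 to 482 CPM in females and 0.121 to 0.420 in males, and with the Y-linked Ddx3y, at 0 in females and 77.2 to 95.008 in males.

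The libraries also differed by mouse number. The first principal component carried 41.6% of the variance and placed mice 1 to 6 on one side and mice 7 to 12 on the other. The haemoglobin gene Hba-a1 was at 489.9 to 913 CPM in mice 1 to 6 and at 24.4 to 56.1 in mice 7 to 12, the skeletal muscle actin gene Acta1 at 10.2 to 127 against 0.283 to 0.791, and the neutrophil gene Mpo at 2.12 to 5.42 against 0.0610 to 0.231. Dbp, a clock output gene, was lower in mice 1 to 6, at 19.7 to 24.03 against 33.4 to 46.6. These 4 genes were chosen after their values were seen, and Hba-a1 shares 57.5% of its 75-base sequences with other genes. With sex and genotype in the fit, 1356 genes differed between the 2 sets of mice, 848 higher and 508 lower in mice 1 to 6 (edgeR). Mice 1 to 6 were 3 WT males, 2 ETAQ/+ males and 1 ETAQ/+ female, and mice 7 to 12 were 3 WT females, 2 ETAQ/+ females and 1 ETAQ/+ male. Each set thus held 3 mice of each genotype, while sex and set largely coincided.

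**Figure D1:**
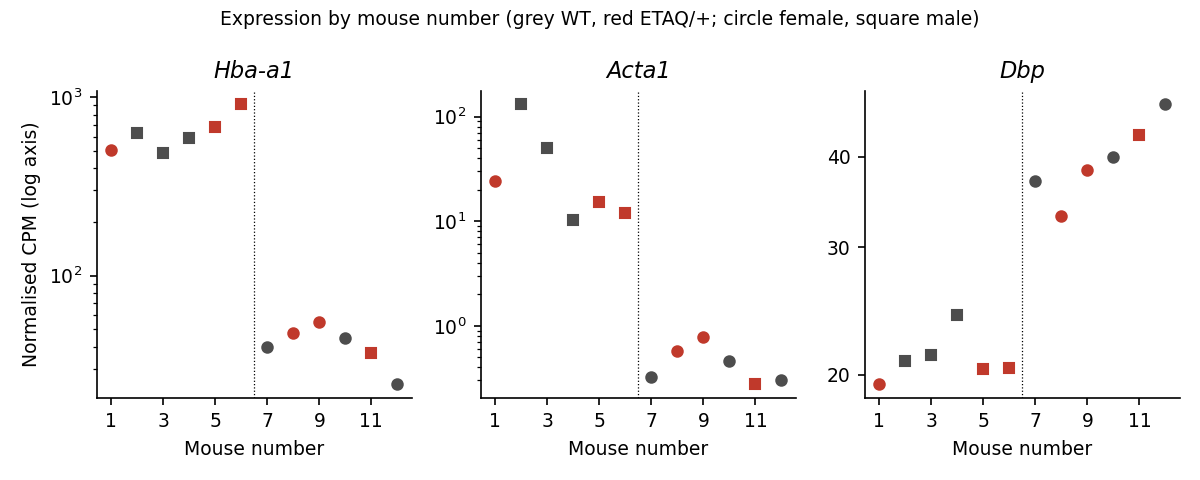
Normalised CPM (log axis) of Hba-a1, Acta1 and Dbp against mouse number, 1 point per mouse, with WT in dark grey, ETAQ/+ in red, females as circles and males as squares. Hba-a1 and Acta1 are higher and Dbp is lower in mice 1 to 6, left of the dotted line, than in mice 7 to 12.

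In ETAQ/+ cords, 21 of 40 targets of ATF4, the transcription factor of the integrated stress response, and 9 of 23 genes for cytosolic tRNA synthetases rose. Of the genes of motor neurons 9 of 19 fell, and of those of neurofilaments and the axonal cytoskeleton 7 of 16. Fgf21 (ENSMUSG00000030827, chromosome 7, 45613886 to 45615490), a stress-induced hormone gene, stood at 7.25 ± 0.806 normalised CPM (n = 6) in ETAQ/+ and at 0.0314 ± 0.0339 in WT (n = 6), where no library held more than 3 counts (log2 fold change 7.66 ± 0.28, adjusted p = 7.12e-10). Chodl (ENSMUSG00000022860, chromosome 16, 78930948 to 78951733), which encodes the membrane protein chondrolectin of fast motor neurons, fell from 44.6 ± 5.62 to 12.5 ± 1.17 (log2 fold change -1.84 ± 0.07, adjusted p = 7.12e-10). Nefl (ENSMUSG00000022055, chromosome 14, 68083863 to 68089095), the light neurofilament chain of axons, fell from 1987 ± 61.0 to 1415 ± 68.4 (log2 fold change -0.49 ± 0.03, adjusted p = 2.18e-07). P2rx3 (ENSMUSG00000027071, chromosome 2, 84998583 to 85037462), an ATP-gated channel of pain-sensing neurons, rose from 1.40 ± 0.274 to 10.4 ± 1.64 (log2 fold change 2.87 ± 0.13, adjusted p = 6.73e-09).

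**Figure D2:**
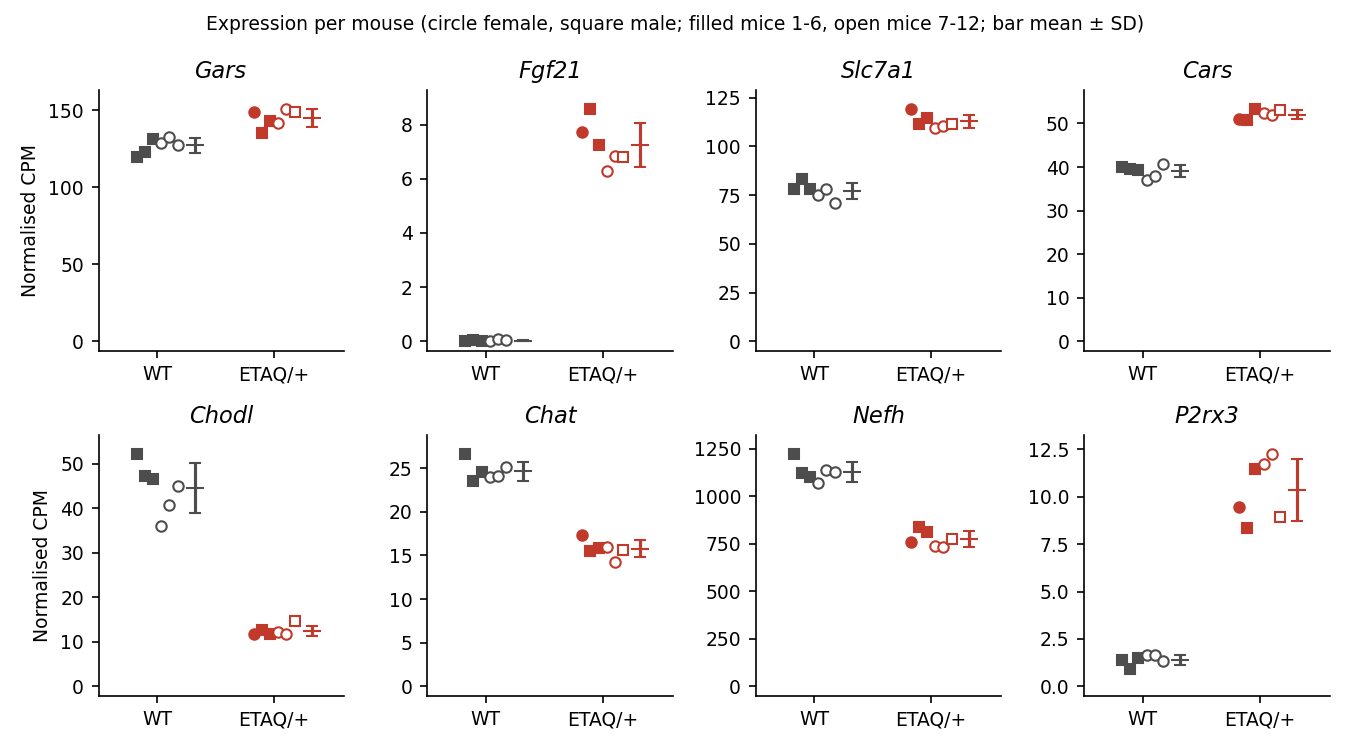
Normalised CPM of 8 genes, 1 point per mouse in WT (dark grey) and ETAQ/+ (red), with females as circles, males as squares, mice 1 to 6 filled, mice 7 to 12 open, and bars for mean ± SD (n = 6). In each panel the values of the 2 genotypes are separate.

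Of 17189 genes tested, 330 differed between the genotypes, 100 higher and 230 lower in ETAQ/+, beside 1873 at an unadjusted p under 0.05. The median absolute log2 fold change of the 330 was 0.31, and 50 of them changed at least 2-fold. All 330 had the same sign of change in both sexes and in both sets of mice. They were called from the effect over these same 12 mice, so this agreement largely follows from the selection. In 248 of them the CPM of the 6 ETAQ/+ mice and the 6 WT mice did not overlap. Over all tested genes 345 (2.01%) were separate in this way, against 0.216% for a random division of 12 mice. In a fit of all 12 libraries with a genotype term for each set, 138 genes were called within mice 1 to 6 (48 higher, 90 lower), and within mice 7 to 12, 161 (43 higher, 118 lower). These calls shared 106 genes, all in the same direction, where independent lists would share 0.738. The effects of the 2 sets are not fully separate, since the sex term of that fit rests on ETAQ/+ mice of both. With mouse number as a covariate 465 genes were called, 151 higher and 314 lower.

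The list of ATF4 and integrated stress response targets held 40 tested genes, of which 21 rose and 19 did not pass. Adjusted over the list alone, 29 passed, all higher. The list as a whole was higher by camera (adjusted p = 4.3e-39), and with an estimated correlation the adjusted p was 0.00152. Slc7a1 and Slc7a3, transporters of cationic amino acids, rose by log2 0.55 ± 0.04 (adjusted p = 2.84e-07) and 0.82 ± 0.07 (adjusted p = 1.14e-05). Atf4 itself rose by 0.41 ± 0.04 (adjusted p = 1.43e-05), Chac1, which degrades glutathione, by 0.73 ± 0.07 (adjusted p = 1.6e-05), and Sesn2, a nutrient-sensing gene that is also on the list of p53 targets, by 0.36 ± 0.04 (adjusted p = 7.15e-05). Chosen after their values were seen, the peptide hormone gene Adm2 had 100 counts over the 6 ETAQ/+ libraries and 0 over the WT libraries, which is at least 36.6-fold higher when WT is set to a floor of 3 counts over the group. Also chosen after their values were seen, the stress cytokine gene Gdf15 was at 0.562 ± 0.173 against 0.0446 ± 0.0417 normalised CPM (adjusted p = 0.000651), and the asparagine synthetase gene Asns rose by 0.27 ± 0.03 (adjusted p = 0.000453).

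Of 23 tested genes for cytosolic tRNA synthetases and their scaffold, 9 rose, Gars among them, and 14 did not pass. Adjusted over the list alone, 13 were higher and 1 lower. The list was higher by camera (adjusted p = 3.15e-11), and with an estimated correlation the adjusted p was 0.0256. The cysteinyl enzyme gene Cars rose from 39.1 ± 1.38 to 52.0 ± 1.07 normalised CPM (log2 fold change 0.41 ± 0.03, adjusted p = 1.44e-06). The genes for the methionyl, isoleucyl and leucyl enzymes, Mars, Iars and Lars, rose by 0.28 ± 0.03 (adjusted p = 0.000189), 0.22 ± 0.03 (adjusted p = 0.000516) and 0.18 ± 0.03 (adjusted p = 0.00159). The list of mitochondrial synthetases, which leaves out Gars, held 17 tested genes. Of these edgeR called 0, with 0 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom.

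**Figure D3:**
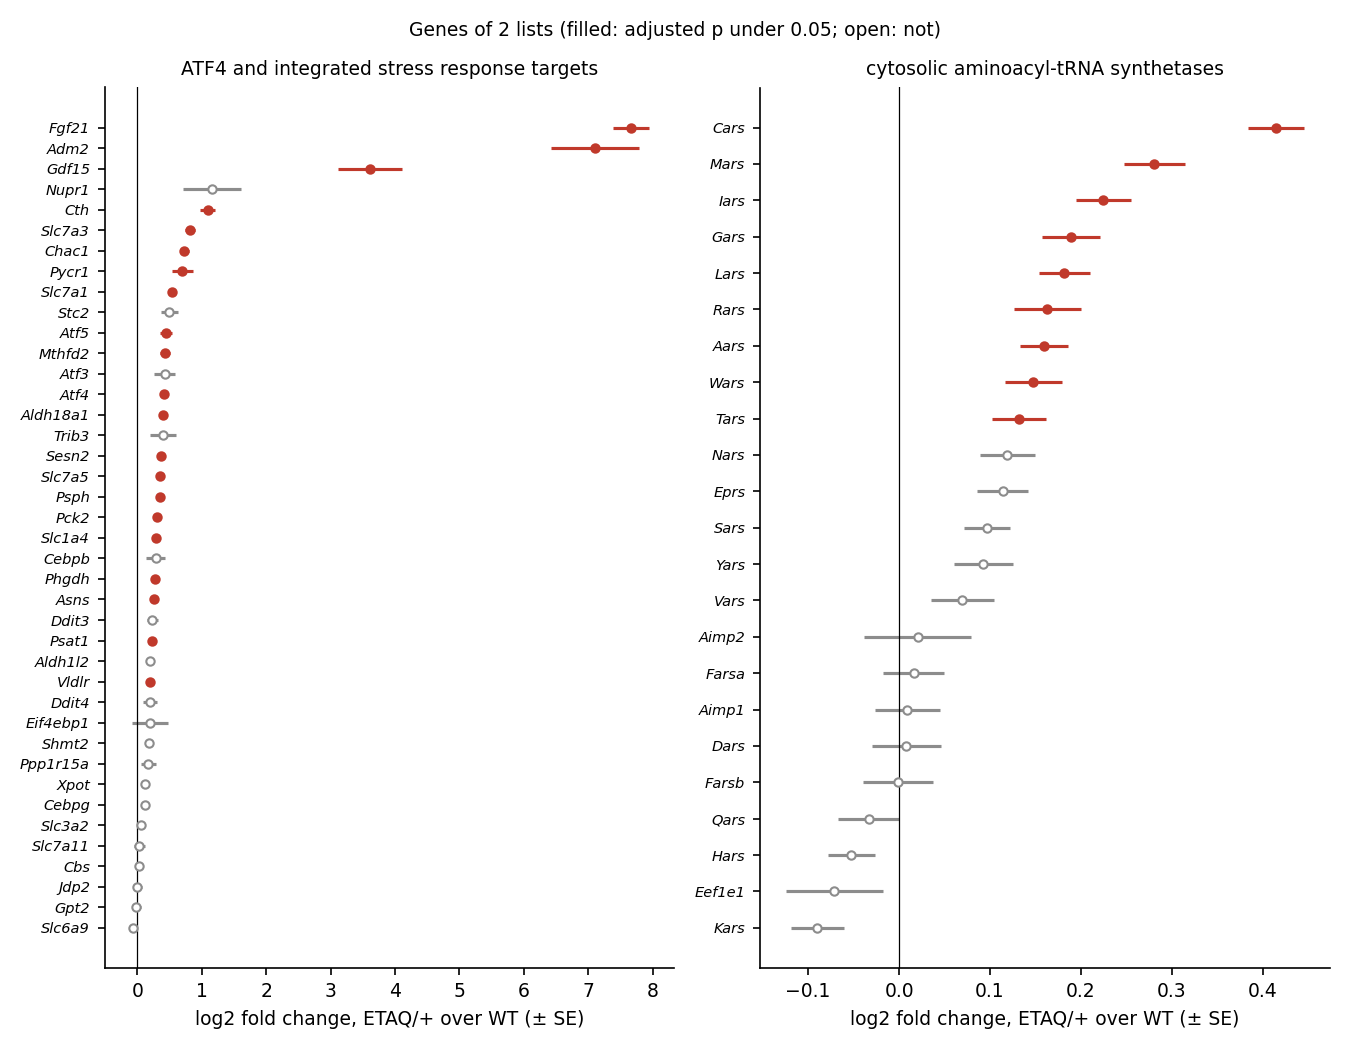
Log2 fold change (ETAQ/+ over WT) ± SE, horizontal axis, of each tested gene of the integrated stress response list (left) and the cytosolic synthetase list (right), filled where the adjusted p is under 0.05. All filled points, 21 on the left and 9 on the right, lie to the right of 0.

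Of 19 tested motor neuron and cholinergic genes, 9 fell and 10 did not pass. Adjusted over the list alone, 14 were lower and 1 higher. The list was lower by camera (adjusted p = 2.39e-18), and with an estimated correlation the adjusted p was 0.00695. Chat (ENSMUSG00000021919, chromosome 14, 32408203 to 32465989), the enzyme that makes acetylcholine, fell from 24.6 ± 1.12 to 15.8 ± 0.978 normalised CPM (log2 fold change -0.64 ± 0.05, adjusted p = 2.62e-06). Prph, the peripheral intermediate filament peripherin, changed by -0.84 ± 0.05 (adjusted p = 2.84e-07), Ahnak2, a large scaffold protein gene, by -1.13 ± 0.08 (adjusted p = 1.6e-05), and Calca, which encodes the neuropeptide CGRP, by -2.06 ± 0.16 (adjusted p = 1.68e-05). Other members stayed above the threshold in edgeR: the choline transporter gene Slc5a7 was at -0.28 ± 0.08 (adjusted p = 0.138) and the motor neuron transcription factor gene Mnx1 at -0.14 ± 0.12 (adjusted p = 0.779), both chosen after their values were seen. DESeq2 called 10 members, with Slc5a7 added.

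Of 16 tested genes for neurofilaments and the axonal cytoskeleton, 7 fell and 9 did not pass, and adjusted over the list alone 8 passed, all lower. The list was lower by camera (adjusted p = 2.6e-16), and with an estimated correlation the adjusted p was 0.00695. The 3 neurofilament chains fell by similar amounts: beside Nefl, the medium chain Nefm changed by -0.55 ± 0.04 (adjusted p = 1.23e-06) and the heavy chain Nefh (ENSMUSG00000020396, chromosome 11, 4938754 to 4948064) by -0.54 ± 0.03 (adjusted p = 2.32e-07). Nefl and Nefm lie on opposite strands and share 1108 exon bases, 32.8% of those of Nefl and 19.2% of those of Nefm, and since the strand setting was not given, reads in that part cannot be assigned to either gene. Prph is a member of this list too. Calls of both neuron lists lay partly on chromosome 14, described below: 2 of the 9 motor neuron calls and 2 of the 7 cytoskeleton calls.

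**Figure D4:**
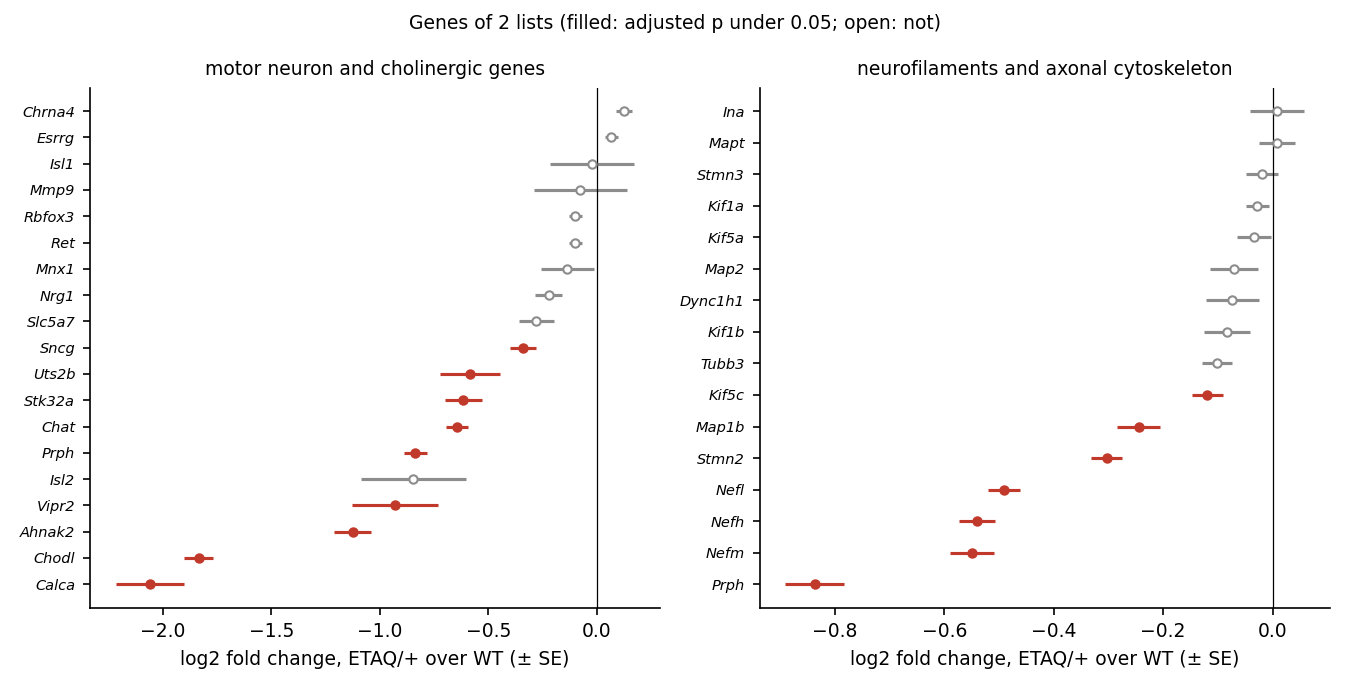
Log2 fold change (ETAQ/+ over WT) ± SE, horizontal axis, of each tested gene of the motor neuron and cholinergic list (left) and the neurofilament and axonal cytoskeleton list (right), filled where the adjusted p is under 0.05. All filled points, 9 on the left and 7 on the right, lie to the left of 0.

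Among 10 tested sensory ganglion genes, 4 passed in opposite directions, also when adjusted over the list alone, and camera did not call the list (adjusted p = 0.92). P2rx3 and the actin-binding protein gene Avil (log2 fold change 2.35 ± 0.32, adjusted p = 0.000934) rose, and Prph and Calca fell. Outside the lists, the genes with the smallest p included the epidermal adhesion gene Cdsn, which rose from 0.160 ± 0.0631 to 4.09 ± 0.534 normalised CPM (adjusted p = 8.66e-09), the glycogen-binding protein gene Stbd1 (log2 fold change 1.62 ± 0.10, adjusted p = 2.84e-07) and the glycosyltransferase gene B4galnt2 (4.75 ± 0.33, adjusted p = 6.07e-07), of whose exon bases 15.3% lie opposite another gene. Lower genes were Dffa, the inhibitor of the caspase-activated nuclease (-0.57 ± 0.03, adjusted p = 4.04e-08), Susd2 (-0.59 ± 0.03, adjusted p = 1.16e-07), the sodium pump regulator Fxyd7 (-0.76 ± 0.05, adjusted p = 2.32e-07), the potassium channel gene Kcnj14 (-1.01 ± 0.07, adjusted p = 4.45e-07) and Slc10a4, a vesicular transporter of cholinergic and monoaminergic neurons (-0.86 ± 0.06, adjusted p = 6.07e-07). Dffa, Kcnj14 and Slc10a4 share 6.47%, 27.1% and 18.5% of their 75-base sequences with other genes and are uncertain to that extent.

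Single members of glial and neuronal lists passed without a call of the list by camera. The astrocyte genes Agt, the angiotensin precursor, and Slc1a3, a glutamate transporter, rose by 0.24 ± 0.04 (adjusted p = 0.00194) and 0.19 ± 0.04 (adjusted p = 0.0141), the 2 calls among 14 astrocyte genes (camera adjusted p = 0.143), with 4 higher and 1 lower when adjusted over the list alone. Among 21 reactive astrocyte genes the complement gene C3 passed at 0.38 ± 0.09 (adjusted p = 0.0489; camera 0.681), the 1 call also when adjusted over the list alone. Its adjusted p was 0.128 without mouse 8 and 0.0632 with mouse number as a covariate, at the same fold change of 0.38. Spp1, the osteopontin gene, which motor neurons also express, was the 1 call among 17 genes of disease-associated microglia (-0.42 ± 0.05, adjusted p = 0.000527; camera 0.829). In that list 1 higher and 1 lower gene passed when adjusted over the list alone, and 18.8% of the Spp1 exon bases lie in another gene on the same strand. Spp1 also shares 9.32% of its 75-base sequences with other genes and is uncertain.

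Of 15 glutamatergic neuron genes, Reln, an extracellular matrix glycoprotein gene, rose by 0.23 ± 0.05 (adjusted p = 0.0198) and the transcription factor gene Maf was at -0.19 ± 0.04 (adjusted p = 0.0338; camera 0.824), the same numbers as when adjusted over the list alone. The synaptic vesicle gene Sv2b passed among 18 synaptic genes (-0.23 ± 0.03, adjusted p = 0.000344; camera 0.141; 3 lower when adjusted over the list alone). The sodium channel subunit gene Scn4b passed among 18 voltage-gated channel genes (-0.13 ± 0.03, adjusted p = 0.0224; camera 0.143; 1 lower when adjusted over the list alone). The GDNF receptor gene Gfra1 passed among 15 neurotrophin and semaphorin receptor genes (-0.23 ± 0.04, adjusted p = 0.00173; camera 0.775; 1 higher and 4 lower when adjusted over the list alone). The glutathione transferase gene Gsta4 passed among 14 NRF2 targets (-0.18 ± 0.04, adjusted p = 0.0424; camera 0.114; 1 lower when adjusted over the list alone), and Sesn2 among 14 p53 targets (camera 0.681; 1 higher when adjusted over the list alone). Reln, Maf, Scn4b and Gsta4 lay close to the threshold: without mouse 8 their adjusted p was 0.0622, 0.0941, 0.0736 and 0.118.

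Camera at the preset correlation also placed 5 further lists lower, and with an estimated correlation the adjusted p was 0.981 for each. Of 18 cholesterol synthesis genes (preset adjusted p = 0.00459), Mvk, the mevalonate kinase gene, and Nsdhl, a sterol dehydrogenase gene, passed at -0.22 ± 0.04 (adjusted p = 0.0123) and -0.17 ± 0.04 (adjusted p = 0.0442), and 2 passed when adjusted over the list alone. The adjusted p of Nsdhl was 0.122 without mouse 8. In the other 4 lists edgeR, DESeq2 and limma-voom called 0 members, and 0 passed when adjusted over the list alone: 15 skeletal muscle genes (preset adjusted p = 7.14e-06, 0 at an unadjusted p under 0.05), 13 mitochondrially encoded genes (0.00141, 0 at an unadjusted p under 0.05), 21 nuclear oxidative phosphorylation genes (0.0474, 4 at an unadjusted p under 0.05) and 18 proteasome genes (0.000706, 7 at an unadjusted p under 0.05). The members with the smallest p were Psmb2 at -0.14 ± 0.04 and Psmc1 at -0.10 ± 0.03, mt-Nd2 at -0.20 ± 0.10 and mt-Cytb at -0.13 ± 0.07, Cox4i1 at -0.09 ± 0.03 and Atp5b at -0.07 ± 0.03, and Myh7 at -0.37 ± 0.24 and Pvalb at -0.16 ± 0.16. Psmc1 and Myh7 are uncertain, with 6.42% and 11.1% of their 75-base sequences shared. The skeletal muscle list moved with mouse number, with 12 of its 15 members higher in mice 1 to 6. With mouse number as a covariate camera still placed it lower at the preset correlation (adjusted p = 0.00182), but not with an estimated correlation (0.943).

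The 23 remaining lists, with 330 members in all, had no member past the threshold in edgeR, against 24 at an unadjusted p under 0.05, 6 called by DESeq2 and 0 by limma-voom. They covered the mitochondrial synthetases, ATF6 and XBP1 targets, the heat shock response, axon injury, inhibitory neurons, mature oligodendrocytes, oligodendrocyte precursors, homeostatic microglia, the interferon response, antigen presentation, border-associated macrophages and leukocytes, endothelium, pericytes and smooth muscle, fibroblasts, ependymal cells, Schwann cells, red blood cells, bone with cartilage and fat, cytosolic ribosomal proteins, the core clock, immediate early genes, glucocorticoid targets and Hox genes. With mouse number as a covariate edgeR called 6 members, Hspe1 and Fabp7 higher and Bag3, Anxa2, Itm2a and Mfsd2a lower, named after their values were seen except Anxa2. Hspe1 shares 13.8% of its 75-base sequences with other genes and is uncertain. Without the mouse number covariate, the camera adjusted p ranged from 0.0607 to 0.990, and 3 members passed when adjusted over a list alone. Among 19 axon injury genes the smallest p belonged to the growth factor gene Csf1 (0.15 ± 0.04, adjusted p = 0.131) and the annexin gene Anxa2 (-0.47 ± 0.14, adjusted p = 0.178), of which DESeq2 called Anxa2. With mouse number as a covariate Anxa2 was called by edgeR too, at -0.49 (adjusted p = 0.002). In 10 lists the median or the mean of the log2 fold changes and the direction given by camera differed in sign, none of them called: axon injury, inhibitory neurons, border-associated macrophages and leukocytes, fibroblasts, Schwann cells, sensory ganglion, red blood cells, glucocorticoid targets, Hox genes and neurotrophin receptors. With mouse number as a covariate camera turned from lower to higher for the red blood cell list and called it (adjusted p = 0.0043, and 0.875 with an estimated correlation). Without a call, it also turned from lower to higher for border-associated macrophages and leukocytes and for Schwann cells, and from higher to lower for axon injury.

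Since the background was mixed, calls near Gars were counted. Within 10 Mb of Gars, 3 of 113 tested genes were called (2.65%), against 314 of 16215 elsewhere on the autosomes (1.94%), an odds ratio of 1.38 (95% confidence interval 0.279 to 4.18, Fisher's exact test, p = 0.485). The 3 were Gars, Sspo and Tril, the latter pair named after their values were seen. Nnt, a mitochondrial transhydrogenase gene whose function is lost in B6J and kept in FVB, stood at 27.9 ± 0.965 normalised CPM in ETAQ/+ and 27.1 ± 6.51 in WT (log2 fold change 0.04 ± 0.15, adjusted p = 0.967), with WT mouse 2 at 36.4 and WT mouse 3 at 16.03. It shares 48.7% of its 75-base sequences with another annotated gene.

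Chromosome 14, looked at after the calls were seen, held 53 calls among 635 tested genes (8.35%), against 1.69% of the genes on other chromosomes (Fisher's exact test, odds ratio 5.28, adjusted p = 3.18e-18 over 20 chromosomes). The calls, 17 higher and 36 lower, lay between 3.13 and 74.7 Mb, from Gm10340 (87.1% of its 75-base sequences shared) to the serotonin receptor gene Htr2a, and in 38 the genotypes did not overlap. This stretch holds Chat, Nefm and Nefl. Of the 53, 31 share at least 5% of their 75-base sequences with other genes, among them Gm3411 (81.6%), which rose from 13.4 ± 2.10 to 27.3 ± 1.15 normalised CPM (adjusted p = 2.81e-06), Gm3002 (91.6%), which rose by log2 0.78 ± 0.07 (adjusted p = 1.41e-05), and Tmem254a and Tmem254b (74.5% and 100%), which had identical values of 8.13 ± 0.952 in ETAQ/+ and 19.9 ± 2.06 in WT (adjusted p = 2.18e-07). RSEM can divide reads among such copies, so the single genes are uncertain. Chromosome 17 held fewer calls than the rest, 5 of 828 (0.604%, adjusted p = 0.0178).

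**Figure D5:**
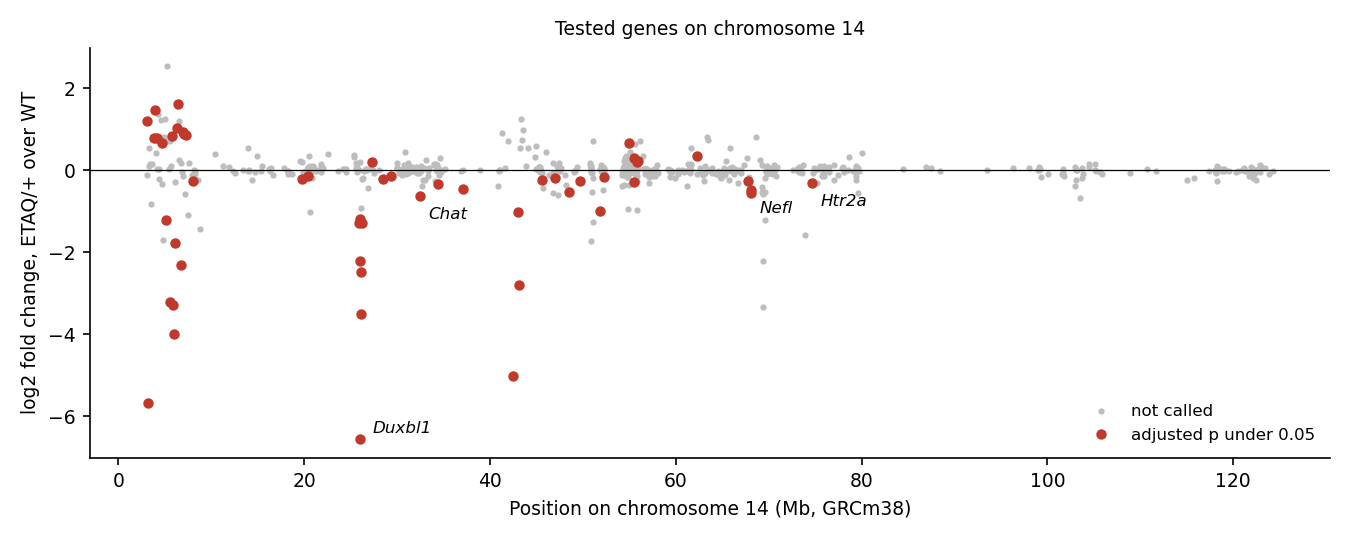
Log2 fold change (ETAQ/+ over WT, vertical axis) of each tested gene on chromosome 14 against its position in Mb (GRCm38), with called genes in red and the others in grey. The 53 called genes lie between 3.13 and 74.7 Mb, and the last of them is Htr2a.

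The same genes led in each sex. In females Fgf21 rose by log2 7.17 (adjusted p = 3.65e-07), Chodl was at -1.77 (adjusted p = 3.65e-07) and Nefl at -0.53 (adjusted p = 1.23e-05), and in males Fgf21 rose by 8.27 (adjusted p = 1.46e-07), Chodl was at -1.90 (adjusted p = 1.46e-07) and Nefl at -0.45 (adjusted p = 4.72e-05), each with n = 3 mice per genotype. Atf4 rose by 0.46 (adjusted p = 0.000376) in females and 0.36 (adjusted p = 0.0029) in males. Gars was at 0.18 (adjusted p = 0.135) and 0.19 (adjusted p = 0.105). In all, 127 genes were called in females (34 higher, 93 lower; 1521 at an unadjusted p under 0.05) and 115 in males (39 higher, 76 lower; 1487 at an unadjusted p under 0.05). Of these, 82 were called in both sexes in the same direction, where independent lists would share 0.488, and 127 of 127 female calls and 113 of 115 male calls had the same sign in the other sex. Across all tested genes, which are not independent replicates, the correlation of the 2 effects was -0.01, and that of the effects within mice 1 to 6 and within mice 7 to 12 was 0.25.

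Of the 6 lists of neighbouring tissue, all had a median log2 fold change above 0 in females, and 4 had one well below 0 in males. The medians in females and males were 4.56 and -2.70 for skeletal muscle, 2.58 and -0.62 for border-associated macrophages and leukocytes, 0.84 and -0.70 for fibroblasts, 0.72 and -0.33 for Schwann cells, 2.499 and -0.04 for red blood cells, and 2.75 and 0.02 for bone, cartilage and fat. Of mice 1 to 6, 1 is an ETAQ/+ female and none is a WT female, while 2 are ETAQ/+ males and 3 are WT males. With mouse number as a covariate, 161 genes were called in females and 138 in males. These equal the calls within mice 7 to 12 and within mice 1 to 6, since females of mice 1 to 6 and males of mice 7 to 12 were of 1 genotype only. Counts depended on single mice: without mouse 1, 7, 8, 9, 10 or 12 the female count was 84, 80, 84, 80, 72 or 69, and without WT mouse 2 or 3 the male count was 67 or 74.

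The difference between the sexes was tested for each gene. For Fgf21 it was -1.10 (females minus males, log2; adjusted p = 0.923), for Chodl 0.13 (adjusted p = 0.929), for the transporter gene Slc7a3 0.15 (adjusted p = 0.923), for P2rx3 -0.07 (adjusted p = 0.984), and for Nefl it was -0.09 (adjusted p = 0.903). edgeR called 0 genes for the interaction, with 852 at an unadjusted p under 0.05, DESeq2 called 0 (829 at an unadjusted p under 0.05) and limma-voom 0 (830). In simulated data this test called 64% of genes that differed 2-fold between the sexes. It called 41.7% of those that differed 1.5-fold and 4.08% of those that differed 1.2-fold. Genes that also differ between the sets of mice were not simulated apart, so these shares do not describe them. The sets held unequal shares of the sex and genotype groups, so the interaction is partly confounded with the set. With mouse number as a covariate edgeR also called 0 genes (683 at an unadjusted p under 0.05). All WT males are among mice 1 to 6 and all WT females among mice 7 to 12. In that fit a genotype effect that differs by sex is thus the same contrast as one that differs by set. It cannot tell the 2 apart. Without that covariate the skeletal muscle list, with medians of 4.56 in females and -2.70 in males, held no interaction call. Without WT mouse 4, Kctd12 was called (1 gene), and without ETAQ/+ mouse 8, Aqp4, the water channel gene of astrocytes, and D3Ertd751e were called, genes chosen after their values were seen.

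Between females and males, the X-inactivation RNA Xist and the Y-linked genes differed most. Xist was higher in females by log2 10.80 (adjusted p = 9.67e-14), and Ddx3y, Eif2s3y, Kdm5d and Uty, which have X-linked partners, were at 0 to 0.0730 CPM in females and at 17.9 to 95.008 in males. Of 16 genes called, 10 were higher and 6 lower in females, beside 2884 at an unadjusted p under 0.05. Kdm6a, Eif2s3x, Ddx3x and Kdm5c, which escape X inactivation, were higher in females by 0.51, 0.63, 0.48 and 0.36, and were named after their values were seen. The autosomal calls were Npy2r, a neuropeptide Y receptor gene (log2 0.62, 5.25 ± 0.520 normalised CPM in females and 3.40 ± 0.285 in males, n = 6 each, adjusted p = 0.00786), the kinase anchor gene Akap5 (0.35, adjusted p = 0.0197), the enkephalin gene Penk (-0.25, adjusted p = 0.0489) and the steroid reductase gene Srd5a2 (-1.39, adjusted p = 0.0497). Srd5a2 and Eif2s3x are uncertain, with 5.38% and 32.7% of their 75-base sequences shared with other genes.

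Sex was largely confounded with the set of mice, since 5 of 6 males were among mice 1 to 6 and 5 of 6 females among mice 7 to 12. With mouse number as a covariate, edgeR called 9 genes. The edgeR adjusted p of the 4 autosomal genes became 0.430 for Npy2r, 0.695 for Akap5, 0.632 for Penk and 0.433 for Srd5a2. Their log2 differences were 0.44, 0.27, -0.24 and -1.51, beside 0.62, 0.35, -0.25 and -1.39 without the covariate. WT mice cannot separate sex from set, so only the ETAQ/+ mice do so in that fit. The higher adjusted p values thus do not show that these differences are absent. Without mouse 1 the sex count was 1018 and without mouse 11 it was 1180.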

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

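Apart from the thinning of the libraries, which was planned before its result was seen, the tests below were chosen only after the results they address were seen. In 11 of 112 groups of 6 mice, formed for the named genes outside the sex comparison, 1 mouse lay far from the other 5, where chance alone gives about 1 in 20. In normalised CPM, with the range of the other 5 mice in parentheses, these were Chodl in ETAQ/+ mouse 11 at 14.7 (11.7 to 12.6), Tmem254b and Tmem254a in ETAQ/+ mouse 6 at 10.05 (7.49 to 7.89), Nefm in WT mouse 2 at 2643.5 (2252 to 2349), Gm3411 in WT mouse 10 at 17.6 (11.9 to 13.3), Mars in ETAQ/+ mouse 6 at 60.4 (54.5 to 56.4) and Csf1 in ETAQ/+ mouse 6 at 63.8 (57.4 to 59.2). The others were Psmc1 in WT mouse 7 at 153 (164 to 171), mt-Nd2 in WT mouse 2 at 6264.5 (4287 to 4762) and in ETAQ/+ mouse 5 at 5406 (3816 to 4337), and Myh7 in WT mouse 3 at 14.2 (5.25 to 7.13). Tmem254a and Tmem254b have identical values and count as 1 observation, and with Gm3411, Psmc1 and Myh7 they share at least 5% of their 75-base sequences with other genes and are uncertain.

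Calls for genotype gathered on chromosome 14. Reads shared between near-identical copies do not account for all of it, since among genes with under 5% shared 75-base sequences and in no list, chromosome 14 still held 17 calls among 491 genes against 207 among 13872 elsewhere (odds ratio 2.37, 95% confidence interval 1.34 to 3.92, Fisher's exact test, adjusted p = 0.033). Of these 491 genes, 103 follow the last call, against a median of 34 when the calls are placed at random (permutation p = 0.0332). This end without calls was seen before it was tested, so the p restates it and supports no explanation. Gars lies on chromosome 6, and the alleles carried on chromosome 14 cannot be read from these counts. A stretch that differs by strain between the genotype groups and an effect of the genotype itself both stay open.

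Genes of motor neurons were lower in ETAQ/+, but unequally. An equal lowering of all 19 genes, as from an even loss of motor neurons that are their only source, is argued against by an exact permutation p of 0.005 (2 of 400 sex-stratified splits, the smallest possible). The position of list members on chromosome 14 is argued against as the whole cause. Without that chromosome's genes the list was still lower (camera with estimated correlation, adjusted p = 0.00606). An effect of that chromosome on genes elsewhere was not tested. Lower transcription in motor neurons that remain, loss of a subset of them, and a share of these transcripts from other cells stay open, and cell numbers were not measured.

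Mice 1 to 6 differed from mice 7 to 12, and the labels give no batch. RNA of tissue around the cord may account for part of the 848 genes higher in mice 1 to 6, but was not examined for the 508 lower ones. Of 73 members of 6 lists of neighbouring tissues, 59 were higher there (80.8%), against 5 of 125 members of 8 lists of cord neurons and glia. Members of a list can vary together, so they are not separate observations. By camera each of the 6 lists was higher at the preset correlation. With an estimated correlation the adjusted p was 0.0284 for macrophages and leukocytes, 0.0393 for red blood cells and 0.0284 for bone, cartilage and fat. It was 0.0831 for Schwann cells, 0.173 for fibroblasts and 0.381 for skeletal muscle. Other lists varied. Of 14 antigen presentation genes 9 were higher and of 13 endothelial genes 5, with 0 lower in each, while axon injury genes had 1 higher and 3 lower. Among the 59 were Hba-a1 (489.9 to 913 CPM against 24.4 to 56.1) and Acta1 (10.2 to 127 against 0.283 to 0.791). Hba-a1 shares 57.5% of its 75-base sequences with other genes. In mice 7 to 12, 34 of the 73 stood at 1 CPM or more in every mouse, so the cord samples there hold some of these transcripts too. Sequencing depth is argued against, since 1279 genes were called after thinning each library to the smallest total. Sex is argued against as the whole cause, since 1356 were called with sex in the fit. Only ETAQ/+ mice separate sex from set there, through female mouse 1 among mice 1 to 6 and male mouse 11 among mice 7 to 12. The kit used for each library was not stated, so a difference between kits stays open. All 3 WT males are among mice 1 to 6 and all 3 WT females among mice 7 to 12, and no biological explanation other than sex was tested.

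Other divisions of the mice were fitted in the same way. For genotype in both sexes, 1 of 100 divisions drawn from 200, the real one, reached 330 genes, and the highest of the others called 3. Chance is thus argued against, at the smallest share that 100 divisions can give. The other divisions mix the genotypes, so genotype differences add to their spread. For the lists with an estimated correlation 1 of 100, again the real one, reached 4 lists (highest other 1), so chance is argued against there to the same extent. With the preset correlation 86 of 100 reached 9 lists (highest other 27), so chance is not excluded for that count. In females and in males 10 divisions are too few for a share under 0.05, and the real counts were 127 and 115 with 0 in the highest other. For sex 3 of 100 reached 16 genes. The highest other, 3533, is the division into mice 1 to 6 and mice 7 to 12, a structure of the samples that sex partly follows, and with mouse number as a covariate 9 genes were called. Of the 7 divisions at least as unequal over the 2 sets as the real one, which is among them, 3 reached 16 genes, so chance is not excluded for that count. For the interaction the real count was 0, which all 100 of 100 divisions reach by construction, so this says nothing about chance. The highest other called 3465 genes, with mice 1, 5, 6, 7, 10 and 12 on one side, and there the interaction follows the 2 sets of mice, which points to the same structure.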

How the results depend on the processing

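The mouse number covariate, the genotype terms for each set of mice and the removal of chromosome 14 were chosen after seeing the data, and the other alternatives were planned. For genotype, the count of 330 stayed within 1.5 times itself under RLE factors (327), no filter (312), the CPM filter (324), limma-voom (322), no robust shrinkage (331), 1 surrogate variable (437), no sex covariate (277), a threshold of 0.10 (455), the mouse number covariate (465) and without chromosome 14. DESeq2 called 506 (162 higher, 344 lower), which include 328 of the 330. The genotype terms for each set of mice, in a fit of all 12 libraries, called 138 and 161. The sex term of that fit rests on the ETAQ/+ mice of both sets, so neither effect is drawn from its own set alone. DESeq2 also called 228 genes in females, 241 in males and 364 for sex, and 0 for the interaction. For sex, 1 surrogate variable and the mouse number covariate each left 9 genes. For the lists, an estimated correlation and fry each left 4 of 9. The causes were not tested.

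Leaving out each mouse in turn gave 236 to 315 genes for genotype, 69 to 136 in females, 67 to 127 in males, 0 to 2 for the interaction, 11 to 1180 for sex, and 8 to 13 lists. In females the count fell to 84, 80, 84, 80, 72 and 69 without mouse 1, 7, 8, 9, 10 and 12, and in males to 67 and 74 without mouse 2 and 3, where fewer mice carry each estimate. The interaction count was 1 without mouse 4 and 2 without mouse 8. The sex count was 1018 without mouse 1 and 1180 without mouse 11, whose removal makes sex and mouse number overlap further, 1 mouse then remaining on the other side.

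Among the named genes called for genotype, none changed direction under any alternative run. Reln, Scn4b, Maf, Gsta4, Nsdhl and C3 missed the threshold without single mice: Reln without mouse 2, 5, 7, 8 or 12 (adjusted p up to 0.0622, without mouse 8), Scn4b without mouse 6, 8, 10 or 12 (up to 0.0736, without mouse 8), Maf without any mouse but 1 or 4 (up to 0.0941, without mouse 8), Gsta4 without any but 2 or 10 (up to 0.118, without mouse 8), Nsdhl without any but 3, 6 or 7 (up to 0.122, without mouse 8) and C3 without any but 1 or 10 (up to 0.128, without mouse 8). Under the other settings 31 of 495 values missed it. The same 6 genes and Lars, Gars, Mvk and Slc1a3 did so within both sets of mice, Iars within mice 7 to 12 and Gfra1 within mice 1 to 6. Maf, Gsta4 and Nsdhl did so with limma-voom, Maf, Nsdhl and C3 without the sex covariate, and C3 also without a filter, with 1 surrogate variable and with the mouse number covariate. Of genes not called, Anxa2 passed with DESeq2, 1 surrogate variable, the mouse number covariate and without mouse 1 (adjusted p = 0.00596), and Psmb2 without mouse 1 (adjusted p = 0.0484). Nnt reversed to -0.0814 without WT mouse 3 and to -0.0204 within mice 7 to 12, and ranged from -0.0814 to 0.16 over the mice left out, and the cause was not tested. No paired analysis was possible because the groups share no mouse numbers. For a gene with 0 counts in a library, the upper limit of 3 counts is 0.0724 to 0.127 CPM.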

Other observations

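The values here were chosen after they were seen, and no explanation of them was tested. Fev, a transcription factor gene of serotonergic neurons, was at 0.928 normalised CPM in ETAQ/+ and 0.101 in WT (log2 fold change 3.15 ± 0.34, adjusted p = 6.66e-05). Cass4, a focal adhesion scaffold gene, was at 1.66 against 0.260 (2.62 ± 0.27, adjusted p = 4.57e-05), and Fut1, a fucosyltransferase gene at 45617289 to 45621059 on chromosome 7 beside Fgf21, had a log2 fold change of 3.49 ± 0.56 (adjusted p = 0.00272). Lower genes picked from their values were Rspo2, a secreted Wnt modulator gene (-0.82 ± 0.07, adjusted p = 3.55e-06), the potassium channel genes Kcng4 (-0.34 ± 0.05, adjusted p = 0.00258) and Kcnk9 (-0.45 ± 0.06, adjusted p = 0.000384), the motor neuron transcription factor gene Lhx4 (-0.59 ± 0.08, adjusted p = 0.000432) and the CGRP gene Calcb (-1.11 ± 0.16, adjusted p = 0.000868).

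Duxbl1, on chromosome 14, had 1 count over the 6 ETAQ/+ libraries and 193 over the 6 WT libraries. It shares 92.1% of its 75-base sequences with other genes, so its counts are uncertain.

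Gapdh, a common reference gene, ranged from 8.07 to 1385 CPM over the 12 libraries: it was at 8.07, 9.25 and 9.53 in mice 2, 6 and 9, at 1385, 1374 and 1357 in mice 1, 5 and 8, and at 419 to 480.1 in the other 6. Its copies Gm13394 and Gm12033 ranged from 0 to 1179 and from 0.509 to 571, while the sum of the 3 genes ranged from 1358 to 1778. Of their 75-base sequences, 20.6%, 90% and 98.1% occur in other genes.

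Of 19 genes on the Hox list, 4 were higher and 3 lower in mice 1 to 6 than in mice 7 to 12, and camera did not call the list (adjusted p = 0.573, and 0.805 with an estimated correlation). Hoxb4, Hoxc6, Hoxc8 and Hoxa7 were higher, and Hoxd9, Hoxd10 and Hoxa10 lower. Single genes picked for their size of change were Hoxc13, lower by a log2 difference of -5.15 (adjusted p = 0.0141), Hoxc12 of -4.01 (adjusted p = 0.00873), Hotair of -2.72 (adjusted p = 0.00607), Hoxc11 of -1.34 (adjusted p = 0.0298), Hoxd11 of -1.12 (adjusted p = 0.0498) and Hoxd10 of -0.69 (adjusted p = 0.0316), each in the edgeR fit with sex and genotype. Hoxc13 was at 0.0555 ± 0.0922 normalised CPM (SD) in mice 1 to 6 and 1.38 ± 0.808 in mice 7 to 12. Hoxc12 was at 0.205 ± 0.223 and 1.88 ± 0.758. In mice 1 to 6 both stood near the limit of 3 counts (0.0724 to 0.127 CPM), so the size of their fold changes is uncertain. Hoxd11 shares 7.5% of its 75-base sequences with other genes and is uncertain.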
